A study of Mus musculus with 4 samples.

How the data were processed

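Mouse embryonic stem cells of the CCE line, grown without feeder cells in medium with leukemia inhibitory factor, received either a control short hairpin RNA or one against Zfp217, a zinc finger protein. Per the labels' protocols, puromycin at 1 microgram per mL was added 4 days after infection and kept for 5 days, total RNA was broken to about 100 nt, and fragments carrying N6-methyladenosine (m6A) were pulled down with an antibody against m6A. Each arm gave an input library and an immunoprecipitated library, so the series has 4 samples in 4 groups, with 1 library per group. The titles of both immunoprecipitated libraries name Zfp217 beside IP, while their antibody field names m6A; they were taken as m6A pulldowns. Groups were taken from the titles.

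The data analysed here are 1 series-wide peak list. Per the submitters' processing notes, CASAVA 1.4, Bowtie2, MACS 1.4 and the mouse build mm9 were used; which step each tool served is not given in the sources used here. The deposited score column holds 900 in each of the 4206 rows, so it ranks nothing. The deposited columns also give chromosome, start, end, strand, and the number, sizes and starts of the blocks of each peak. Each row further holds a name, used only to tell peaks apart, and a drawn start, a drawn end and a colour, which were not analysed here. The title line calls the list differential peaks. Which libraries were compared and how, and the threshold, are not given in the sources used here. The columns that were analysed do not tell whether a peak rose or fell. The library kit named in the labels does not mark strand, and the sources used here do not say where the strand of each peak came from. Counts and depth per library are unknown, so no interval that needs them is given.

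Positions are printed in mm9, counted from 1. The annotation at hand, GENCODE vM21, is built on GRCm38. Of 486 gaps between blocks, 9 lay at the position of an intron in it, so its positions were not used with those of the list. The design fixed before the data were examined used an annotation only if its build was that of the list. Genes, positions along transcripts, m6A motifs, gene lists and peaks in Zfp217 were therefore not analysed here. After the list had been examined, genes were also sought by comparing gap lengths and distances between peaks with GRCm38 introns. That route carries positions from one build to the other, so it was dropped and none of its output is reported.

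Peaks were described with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and drawn with matplotlib 3.10.9. The length of a peak is the sum of its blocks. Neighbours are peaks of one strand whose blocks lie within 1000 bp of each other, and a cluster is a chain of neighbours. Overlap means at least 1 bp shared between blocks, on either strand. A length was counted as on a step of 30 nt when it was within 1 nt of a multiple of 30. Shares have 95% Wilson binomial intervals, which treat peaks as independent draws; neighbouring peaks are not, and the intervals hold no error between cultures. The measures of step, neighbours, overlap and list order were tested on a simulated list of 2000 peaks, where all 4 were recovered exactly. The simulated peaks were all uninterrupted, so how the measures handle split peaks was not tested. No simulated length was 1 nt off a multiple of 30, and all planted overlaps were on opposite strands. The tolerance and overlap on one strand were therefore not tested either.

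With no fitting annotation, the naming rule fixed before the data were examined takes the 10 widest peaks by position and the 10 highest scores in each direction. The latter part is void because the score is constant and the columns that were analysed give no direction. Width was read as summed block length, a reading made after the list was seen. Clusters, mitochondrial peaks and peaks named for their blocks were chosen after their values were seen. Alternatives fixed in advance merged peaks within 100 bp, left out chromosomes X, Y and M, and left out peaks over 1000 bp.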

Results

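The series asked how lowering Zfp217 bears on m6A in the RNA of mouse embryonic stem cells. It holds an input and an m6A immunoprecipitated library from control cells and the same pair from Zfp217 knockdown cells, 1 library per group. The values available here were the positions of 4206 peaks in a list titled as differential, which names no sample and does not say what was compared. They fell on 4205 distinct positions. There was no replicate, so no difference between arms could be set against an error. The columns that were analysed give no direction, fold, p-value or gene name, and the extent of the Zfp217 knockdown was not analysed here.

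Peaks of the list lay on 21 chromosomes, including X and the mitochondrial genome. Chromosome 2 held 360 peaks, or 8.56% of the list (95% interval 7.75 to 9.44), chromosome 11 held 334 and chromosome 7 held 318. Chromosome 14 held 115 and chromosome X held 62, or 1.47% (1.15 to 1.89). The mitochondrial genome held 5. These counts were not scaled to the length, gene content or transcription of the chromosomes.

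Both strands carried similar numbers of peaks. The plus strand held 2159, or 51.3% (49.8 to 52.8), and the minus strand held 2047. On 4 of the 21 chromosomes the interval of the plus-strand share left out 50%. Chromosome 3 had 61.5% of its peaks on the plus strand (54.2 to 68.3) and chromosome 18 had 61.6% (52.8 to 69.7). Chromosome 15 had 41.9% (34.9 to 49.2) and chromosome 4 had 44.2% (38.7 to 49.8). The intervals are not corrected for the number of chromosomes looked at, and they treat neighbouring peaks as independent. How transcription divides between the strands of each chromosome was not analysed, so shares away from 50% were not read as a strand bias of m6A.

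**Figure D1:**
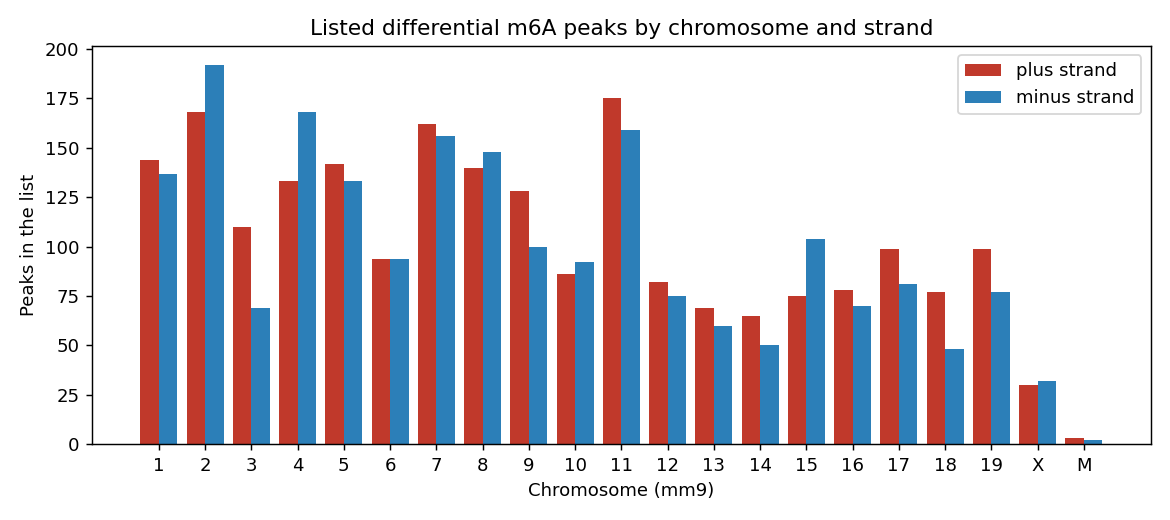
Bars give the number of listed peaks on each mm9 chromosome, with the plus and minus strands side by side. Chromosome 2 held the most peaks, 168 on the plus and 192 on the minus strand.

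Most peaks were single uninterrupted stretches. A single block made up 3801 peaks, while 405 peaks, or 9.63% (8.77 to 10.6), were split into 2 or more blocks. Of these, 333 had 2 blocks, 65 had 3, 5 had 4 and 2 had 5. The 486 gaps between blocks had a median of 1478 bp, with quartiles of 507 and 3161 bp and a largest gap of 90507 bp. The 2 peaks with 5 blocks lay on the minus strand, on chromosome 10 from 116493174 to 116497715 and on chromosome 8 from 88062883 to 88072495.

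Summed over blocks, peaks had a median length of 210 nt, with quartiles of 120 and 420 nt and a range of 58 to 3149 nt. Together the peaks added up to 1.32 Mb, with stretches shared by overlapping peaks counted for each of them. Peaks with 2 or more blocks had a median length of 360 nt against 210 nt for peaks of 1 block, a ratio of 1.71. The most frequent length was 61 nt, seen in 396 peaks, followed by 91 nt in 277 and 121 nt in 195. Lengths within 1 nt of a multiple of 30 were found in 3616 peaks, or 86.0% (84.9 to 87.0), where lengths spread evenly over whole numbers would give 10%. Peaks over 1000 nt numbered 143.

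**Figure D2:**
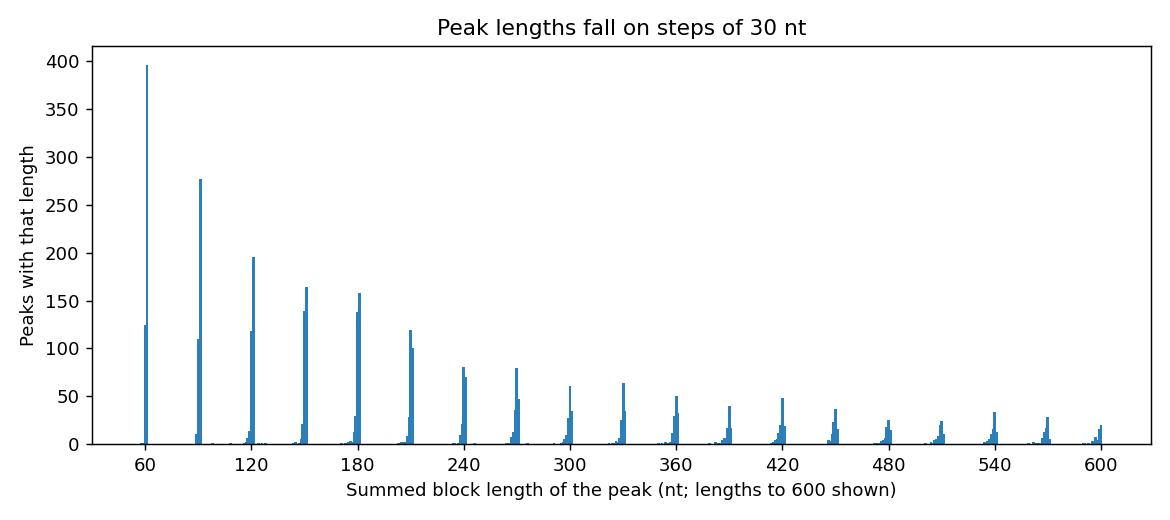
Bars give the number of peaks at each summed block length in nt, for lengths to 600 nt. The tallest bar is at 61 nt with 396 peaks, and later bars gather near multiples of 30 nt. Near 60 nt lengths ran from 58 to 61 nt, and near 570 nt they ran from 559 to 571 nt.

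The widest peak covered 3149 nt in 2 blocks on the minus strand of chromosome 10, from 5987939 to 5991625. The next covered 2773 nt in 2 blocks on the plus strand of chromosome 17, from 88383805 to 88387781. The widest peak of 1 block covered 2458 nt on the minus strand of chromosome 15, from 76006018 to 76008475. It was followed by 2067 nt on the minus strand of chromosome 4, from 133235881 to 133237947, and by 1975 nt on the plus strand of chromosome 8, from 119480187 to 119482161. Chromosome 1 held a peak of 1943 nt on the plus strand, from 135028281 to 135033270, and one of 1856 nt on the minus strand, from 64780843 to 64782698. A peak of 1851 nt lay on the minus strand of chromosome 9, from 106786615 to 106788465. The last of the 10 widest lay on the minus strand of chromosome 18, with 1741 nt from 38748318 to 38750058 and 1732 nt in 2 blocks from 46664648 to 46684091. Width says nothing of the size or direction of a change.

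Peaks often stood close to others on their strand. A neighbour within 1000 bp was found for 1533 peaks, or 36.4% (35.0 to 37.9), which formed 656 clusters. Of the clusters, 506 held 2 peaks and 11 held 5 or more. The cluster with the most peaks, 8, spanned 1.86 kb on the plus strand of chromosome 9, from 111174612 to 111176475, and each of its peaks overlapped another. It joined 4 peaks from each of 2 sorted runs that make up the list, whose meaning is not given in the sources used here. Within the first run, of 4118 peaks, the largest cluster was one of 7 peaks without overlap, which spanned 5.50 kb on the plus strand of chromosome 6, from 4704361 to 4709856. A cluster of 5 peaks spanned 3.15 kb on the minus strand of chromosome 2, from 180393179 to 180396328. No random placement was made, because the transcribed regions of mm9 were not used here. Whether the peaks of a cluster are separate m6A sites was not tested.

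**Figure D3:**
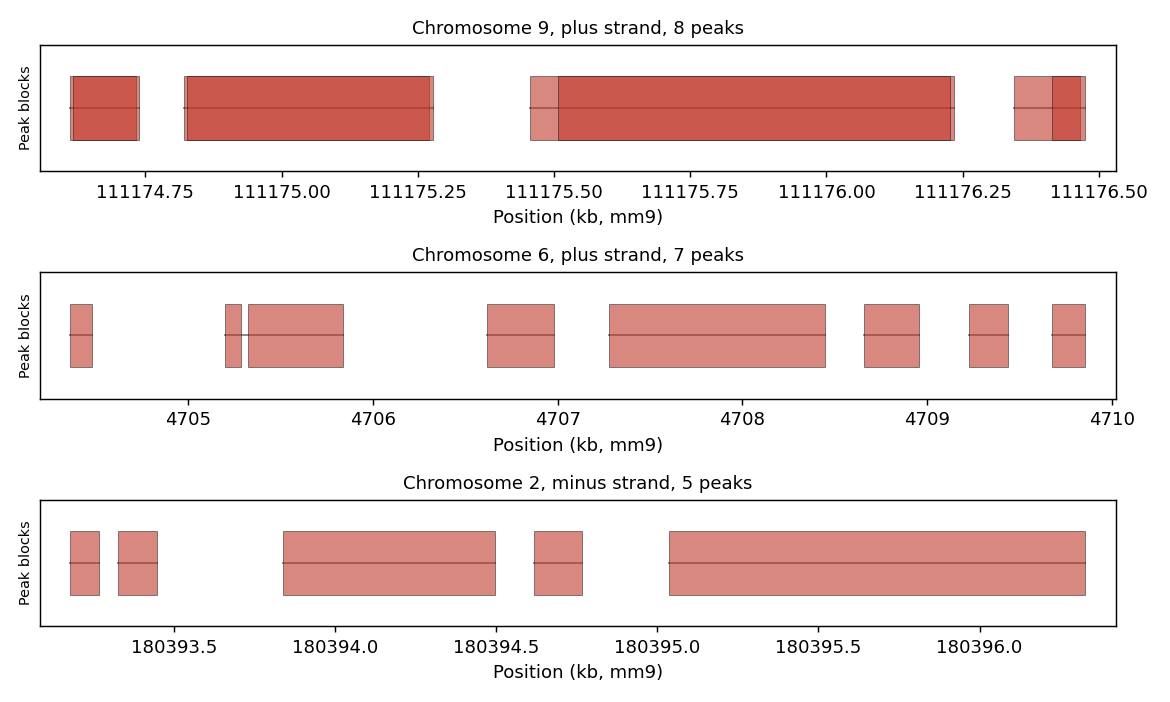
Boxes give the blocks of the peaks in 3 clusters along mm9 positions in kb, drawn to scale, with a line joining the blocks of a split peak. The chromosome 9 cluster is made of overlapping peaks, while the 7 peaks on chromosome 6 and the 5 on chromosome 2 do not overlap.

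The mitochondrial genome carried peaks listed on both strands. On the plus strand they ran from 678 to 852, from 1149 to 1654 and from 2604 to 2693. On the minus strand they ran from 1094 to 1663 and from 2591 to 2681. The latter 2 overlapped plus-strand peaks, both from the second run of 88 peaks. The first run held no overlap there. Since the library kit does not mark strand, the listed strands do not show that RNA from both mitochondrial strands was pulled down.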

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

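Of the 4206 listed peaks, 4139 were left without chromosomes X, Y and M and 4063 without peaks over 1000 bp. Both settings were fixed before the data were examined and only subtract peaks. The limit of 1000 bp was applied to summed block length, a reading of width made after the list was seen. Merging peaks of a strand whose spans overlapped or lay within 100 bp, also fixed before, left 3923. Spans took in the gaps of split peaks, so a peak inside such a gap was joined too. Most peaks joined by merging did not overlap. Selection by score was not run, since the score is constant and could remove or rank nothing. Other settings for genes, transcript positions, motifs, gene lists and Zfp217 were not run because no annotation of the list's build was used here. The other alternatives were chosen after seeing the data. Peaks with a neighbour numbered 1120 at 300 bp, 1741 at 3000 bp and 1475 without the second run of the list. Exact multiples of 30 made up 34.7% of lengths, against 3.33% for evenly spread lengths, and lengths within 2 nt made up 91.7%, against 16.7%; the wider tolerance takes in more lengths by its construction. The overlap of the second run with the first was 25% on one strand against 40.9% on either, since the former leaves out pairs on opposite strands. Without overlapping peaks, 9.68% had 2 or more blocks. No paired analysis was possible because each group has 1 library and the list names none. The depth of the libraries is unknown, so what it limits could not be stated.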

Other observations

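The tests of summed block lengths and of overlapping pairs were chosen after their results had been seen in part, as were the random offsets of those pairs, and the overlap of the runs on one strand was chosen after that on either strand. No biological explanation was tested for any pattern here, since the list ties no value to an arm.

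Lengths near multiples of 30 nt may come from windows moved in fixed steps by the program that called the peaks. Among the 405 peaks with 2 or more blocks, 75.8% (95% interval 71.4 to 79.7) had a summed block length within 1 nt of such a multiple. Only 10.6% (7.98 to 14.0) had a genomic span near one, close to the 10% of evenly spread lengths. This argues against steps that run along the genome across the gaps, and the summed lengths go with steps along joined blocks. Lengths of single blocks were not tested, so steps within each block could not be told apart from steps along joined blocks.

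Overlapping peaks made up 84 pairs, 46 on one strand and 38 on opposite strands. In 91.7% of the pairs (83.8 to 95.9) the shorter peak had at least 80% of its blocks inside the other. The same pairs set at random offsets that still overlap, with each peak taken as uninterrupted, gave 30.1% (21.4 to 39.3 in 95% of 10000 draws). A candidate explanation is that 1 stretch of enrichment was listed more than once. The random offsets do not model how a program places peaks, so they do not test that explanation. The pairs were not split by strand or by the 2 sorted runs of the list. They include the overlaps between runs given below, so the 2 patterns are not separate observations.

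The list is made of 2 runs that each pass through the chromosomes in turn, the first with 4118 peaks and the second with 88. What the runs stand for is not given in the sources used here, and they were not read as directions of change. In the second run, 40.9% of peaks (31.2 to 51.4) overlapped a peak of the first on either strand, and 25% (17.1 to 35.0) did so on their own strand. Within the first run, 2.06% of peaks (1.67 to 2.55) overlapped another of its peaks, which is no chance value for overlap between runs. The bounds set before the share on either strand was seen were above 50% for a repeat of earlier sites and under 10% against one. The share on either strand met neither, so by these bounds the question stays open. Only 36 of the 88 peaks overlapped the first run, so not every peak of the second run repeats an earlier site. In the chromosome 9 cluster, which held 4 peaks of each run, each first-run peak overlapped a second-run peak on the same strand.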
